A study of Homo sapiens with 6 samples.

How the data were processed

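Total RNA from 6 samples of BxPC-3 cells was labelled with Cy3 and measured on 1-colour Agilent whole-genome arrays, with 1 array per sample. By the labels, cells of both groups were kept for 24 h without serum, after which 3 samples were given 10 µM serotonin (5-HT) for 24 h and 3 were untreated controls of the same time point. The labels number the replicates but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Per the file headers, the authors' scanner files hold spot signals as intensity, extracted with Agilent Feature Extraction 10.7.3.1. Its processed signal is background-subtracted and detrended within each array and is not normalized between arrays. The deposited value table holds log2 values. It was normalized between arrays by a method that is not given in the sources used here. Its columns had medians of 6.70 to 6.71 and followed the log2 processed signal of their own arrays with correlations of 0.9992 to 0.9996 across the probes, which are not independent replicates; all 41000 probes were found in both. The headers also show that the 3 control arrays and 5-HT replicate 1 lay on 1 slide and 5-HT replicates 2 and 3 on a second slide, scanned in a second batch.

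The comparison used the processed signal of the scanner files. Each array had 45015 spots, of which 43376 were not controls. Spots that the software marked as non-uniform or as population outliers were left out, 83 to 150 per array, and spots of 1 probe were averaged. The log2 signal of each array was centred on its 75th percentile. Of 41000 probes, 30784 were well above background, as the software calls it, on at least 3 of the 6 arrays in either or both groups. The probe with the highest mean over all 6 arrays stood for each gene, which gave 21984 genes. In 42 of these, a value was left out on at least 1 array. Symbols came from a table of current gene names (GRCh38.p14), used for names only. In it, 14627 genes were matched through the transcript accession, 625 through the name in the file and 158 through an older symbol. The remaining 6574 had no approved symbol and were tested but not named. Probe positions are those of the files, on hg19; no genome sequence was used here.

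Groups were compared with limma 3.58.1 in R 4.3.3 (files read with the package data.table, version 1.17.8), with group as the only term, moderated variances and 2-sided p-values adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05. For a probe below background on every array of 1 group, the change is given as a lower bound. The mean of the brighter group was set against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal well above background on that array. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, and again with an estimated correlation, both adjusted over the 41 lists; fry was run as an alternative. All 41 lists had at least 5 measured members. They covered energy and lipid metabolism, stress responses, the cell cycle and cell death, signalling and inflammation, epithelial and mesenchymal identity, serotonin handling, the circadian clock and markers of other cell types. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

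The groups, the test, the filters, the lists, the alternatives other than 1 added later, and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest rises and the 12 largest falls by fitted difference among changed genes with an approved symbol whose groups did not overlap and which were well above background on all 3 arrays of the brighter group. It also named up to 4 changed members per list with the largest change, and 12 genes tied to serotonin or glycolysis whatever their values. Genes named outside the rule were chosen after their values were seen. Some genes that the rule selects are not reported here by name; they stay in every count and median.

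Alternatives covered the normalization, background correction, probe filter, outlier spots, probe choice, variance model, array weights, threshold, family of genes, list test and value table. Further fits had the replicate number or the slide as a block, or left out each sample in turn. A fit to the slide that holds both groups was added after the data were seen. With slide as a block, the estimate of a gene equals its difference within that slide, since the second slide holds 5-HT samples only, while the spread also draws on the second slide.

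The fit was tested on simulated data with 21984 genes and 3 arrays per group. Of 50 genes changed by 0.5 on the log2 scale, 29 were called in the right direction, with 38 of 50 at 1, 43 of 50 at 2 and 47 of 50 at 3. Of 21784 unchanged genes, 9 were called. Both of the simulated lists of 30 genes shifted by 0.5 were called, and 0 of 20 unshifted lists. The simulated genes were drawn independently of each other and without a slide difference. The list counts therefore do not show how often unshifted lists of correlated genes would be called. Only 200 genes were changed in the simulation, whereas 43.5% of genes were called in the data. The adjusted threshold was thus stricter in the simulation, and its recovery rates do not carry over to the real comparison. The number of arrays limits the precision of every value; the median standard error of a log2 difference was 0.0851.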

Results

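Messenger RNA was measured in BxPC-3 cells, a human pancreatic ductal adenocarcinoma line, in 3 samples given serotonin (5-hydroxytryptamine, 5-HT) and 3 untreated controls. Between 71.9% and 76.9% of the spots on each array were well above background. The 75th percentile of the processed signal ran from 702 to 842 intensity units, and 0 spots were saturated. Replicate spots of a probe on 1 array had a median SD of 0.0456 to 0.0649 on the log2 scale. Across genes, which are not independent replicates, control arrays correlated with each other at 0.992 to 0.993 and with 5-HT arrays at 0.972 to 0.979. The first principal component held 63.2% of the variance and placed the controls at -43.1, -47.7 and -44.9. It placed 5-HT replicate 1, which shared the controls' slide, at 26.2, and replicates 2 and 3, on the second slide, at 56.1 and 53.5.

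The comparison asked which transcripts differed between serotonin-treated and untreated cells. Treated cells held more mRNA for chaperones of the endoplasmic reticulum and for enzymes and transporters of amino acid supply, and less for cholesterol synthesis and DNA replication. With an estimated correlation between genes none of these lists passed (adjusted p = 0.316 for the unfolded protein response, the amino acid response and cholesterol synthesis, and 0.25 for DNA replication). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 2.96 on the log2 scale (SE 0.10, n = 3 per group), and ASNS, which makes asparagine, rose by 3.19 (SE 0.09). HMGCS1, an early enzyme of cholesterol synthesis, fell by 2.71 (SE 0.06), and GINS2, part of the replicative helicase, fell by 1.50 (SE 0.06). SPP1, which encodes the secreted protein osteopontin, had the largest fitted rise, 6.24 (SE 0.12) or 75.6-fold, and TXNIP, an inhibitor of glucose uptake, the largest fitted fall, -4.50 (SE 0.07).

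Of 21984 genes tested, 9574 (43.5%) changed, 4076 up and 5498 down. At least a 2-fold difference was reached by 1368 of them, 678 up and 690 down, and an 8-fold difference by 40 in each direction. The groups did not overlap in 12411 genes (56.5%), where chance gives 10%. The median difference over all genes was -0.07. With normexp background correction and 75th percentile scaling (normexp scaling below) 2244 genes changed, 1146 up and 1098 down. That correction adds 50 intensity units to each signal, which by construction shrinks the log2 differences of dim probes. Median scaling gave 4640 up and 4486 down, so the excess of falls depended on the scaling. Normexp background correction with quantile normalization gave 9546, 4418 up and 5128 down, so the added units alone do not account for the drop to 2244. With slide as a block 6896 genes changed, 6284 of them among the 9574 and in the same direction, and within the slide that holds both groups, where only the 3 controls give the spread, 5438 changed, 5029 of them shared.

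SPP1 (probe on chromosome 4 at 88903920 to 88903979, hg19) had a mean of -3.79 ± 0.21 (SD, n = 3) in controls and 2.45 ± 0.10 (SD, n = 3) with serotonin, in log2 units relative to each array's 75th percentile. TRIM31, a ubiquitin ligase (chromosome 6, 30078391 to 30078450), rose by 5.23 (SE 0.14), and CDH15, a cadherin (chromosome 16, 89261839 to 89261898), by 5.03 (SE 0.13). CXCR4, the receptor of the chemokine CXCL12, rose by 5.01 (SE 0.21) and was above background on 1 of 3 control arrays. CA9, a carbonic anhydrase at the cell surface (chromosome 9, 35677817 to 35679204), rose by 4.54, EDN2, an endothelin, by 4.23, DDIT3, the stress-induced transcription factor CHOP, by 4.01, and DMBT1, a mucosal scavenger protein, by 3.93. In other genes no control array was above background, so that only a bound holds and a place among the largest rises is not shown: the integrin ITGB3 was at least 5.52-fold higher (adjusted p = 1.24e-05), and the glutathione transferases GSTA5 and GSTA1 at least 8.15-fold (8.18e-05) and 8.05-fold (6.52e-05). With normexp scaling ITGB3 and GSTA1 differed by 1.41 and 1.49 and lost their calls (adjusted p = 0.0774 and 0.0617). GSTA1 and GSTA5 are close paralogs whose probes can share signal. TXNIP (chromosome 1, 145442447 to 145442506) had a mean of 5.93 ± 0.03 (SD, n = 3) in controls and 1.43 ± 0.09 (SD, n = 3) with serotonin, and ARRDC4, its relative in the arrestin family (chromosome 15, 98516895 to 98516954), fell by 4.42 (SE 0.12). TNFRSF11B, the decoy receptor osteoprotegerin, fell by 4.18, FGFBP1, a carrier of fibroblast growth factors, fell by 3.95, RFLNA, a filamin-binding protein, fell by 3.77 (by 1.88 with normexp scaling, adjusted p = 0.0566), and TENM2, a teneurin, fell by 3.49.

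Of the 12 largest fitted falls 6 were in genes whose reported probe was not above background on any 5-HT array, so that only a bound holds and a place among the largest falls is not shown. SOSTDC1, an antagonist of BMP signalling, was at least 7.18-fold lower (adjusted p = 3.92e-05), FGFBP2 at least 6.86-fold (0.000182), BBOX1, an enzyme of carnitine synthesis, at least 4.04-fold (0.00012) and CD34 at least 3.91-fold (0.00401). TAAR6, a trace amine receptor, was at least 3.60-fold lower (adjusted p = 0.00889, and 0.0781 with slide as a block), and CLRN3 at least 2.56-fold (0.00443). Within the slide that holds both groups the adjusted p was 0.0789 for CD34, 0.134 for TAAR6 and 0.0845 for CLRN3. With normexp scaling all 6 lost their calls. There SOSTDC1 differed by -0.41 (adjusted p = 0.617), FGFBP2 by -0.38 (0.631), CD34 by -0.13 (0.898) and TAAR6 by -0.0084 (0.993). BBOX1 and CLRN3 differed there by 0.051 and 0.13, of the opposite sign but below that setting's median over all genes, 0.169. Adjusted p-values of the 24 largest fitted changes ran from 1.24e-05 to 0.00889.

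**Figure D1:**
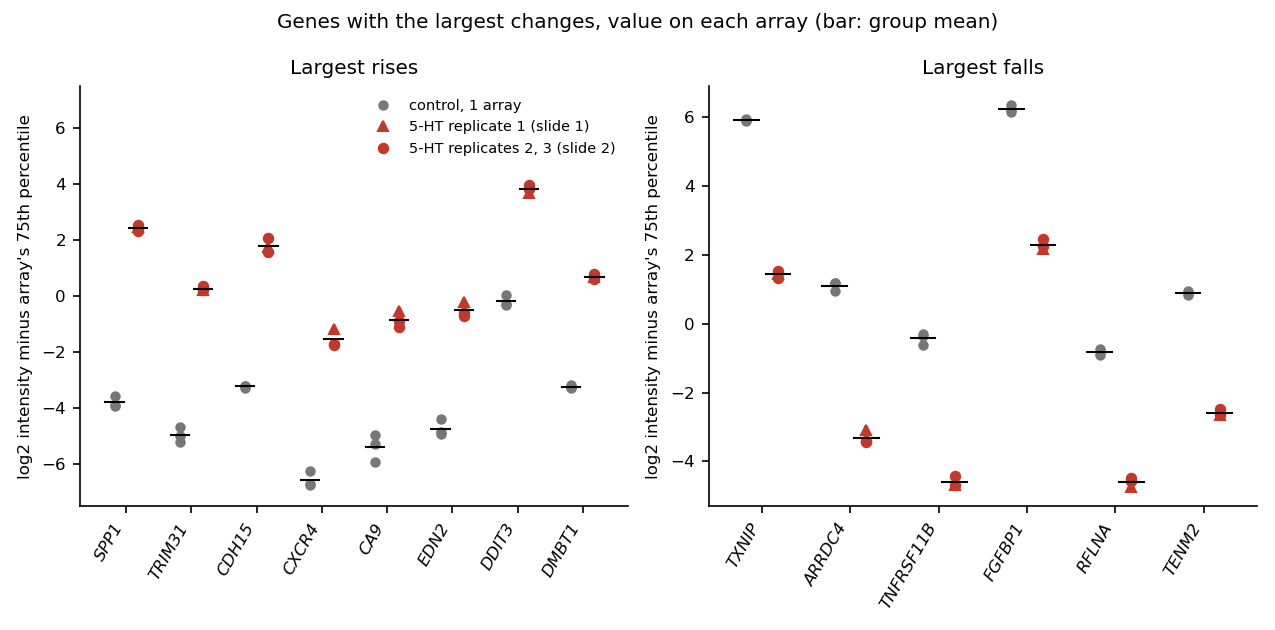
Log2 intensity relative to the array's 75th percentile (vertical axis) on each control array (grey) and each 5-HT array (red, a triangle for replicate 1 on the controls' slide), with bars at group means, for the genes of the 12 largest fitted rises and 12 largest fitted falls that were above background on at least 1 array of each group. SPP1 lay at a mean of -3.79 in controls and 2.45 with serotonin, and TXNIP at 5.93 and 1.43.

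Of 29 measured members of the glycolysis list 16 rose, 0 fell and 13 did not pass (18 rose and 2 fell adjusted over the list alone), with a median of 0.32. The list passed with an adjusted p of 1.48e-05, but adjusted p = 0.25 with an estimated correlation; with slide as a block the median was 0.32 (adjusted p = 3.07e-06). HK2, the hexokinase of the first step (chromosome 2, 75120331 to 75120390), rose by 2.04 (SE 0.07), the enolase ENO2 by 1.91, and PFKFB4 and PFKFB3, which make an activator of phosphofructokinase, by 1.19 and 1.15. Other PFKFB3 probes rose by 3.115, 1.72 and 1.69. The glucose transporter SLC2A1 rose by 0.84 (SE 0.08). LDHA, a subunit of lactate dehydrogenase, differed by 0.19 (SE 0.12, adjusted p = 0.244), and by 0.45 with slide as a block (adjusted p = 0.0144). LDHA also passed with normexp and quantile normalization (0.37, adjusted p = 0.0134) and with its most variable probe (0.35, 0.0193). In the deposited value table it passed at a probe other than the reported one (0.41, 0.0122). A further LDHA probe differed by 0.25 (adjusted p over the probes = 0.0833). The pyruvate kinase PKM differed by -0.06 (SE 0.07, adjusted p = 0.521). Of 29 hypoxia and HIF-1 targets 22 rose, 1 fell and 6 did not pass (23 and 1 adjusted over the list alone), with a median of 0.62 (adjusted p = 6.26e-09). The hypoxia list had adjusted p = 0.519 with an estimated correlation, and a median of 0.87 with slide as a block (adjusted p = 1.6e-12). Besides CA9, the lipase inhibitor ANGPTL4 rose by 2.91 and the lipid droplet protein HILPDA by 1.63, and HIF1A itself rose by 0.40 (adjusted p = 0.0157, but 0.0595 without control replicate 2 and 0.0574 without 5-HT replicate 3). HIF1A and PFKFB4 also lost their calls with normexp scaling (adjusted p = 0.173 and 0.0731). The carbonic anhydrase CA12 fell by 1.64, but was higher by 0.35 in the deposited value table.

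Genes of mitochondrial energy supply went both ways. In the list of the TCA cycle and pyruvate oxidation 5 of 25 rose, 2 fell and 18 did not pass (5 and 2 adjusted over the list alone; median 0.05, adjusted p = 0.344). Pyruvate carboxylase, PC, rose by 0.86 and SDHD, a subunit of succinate dehydrogenase, fell by 0.36. SDHC fell by 0.40 and SDHA rose by 0.26, though with slide as a block and without some single samples these did not pass (adjusted p = 0.092 and 0.0957 for the block). For oxidative phosphorylation 6 of 42 rose, 11 fell and 25 did not pass (6 and 8 adjusted over the list alone; median -0.05, adjusted p = 0.76). With normexp scaling this list did pass, with a median of -0.20 (adjusted p = 0.000225). The complex I subunit NDUFB3 fell by 0.65, NDUFV2 rose by 0.36 and the ATP synthase subunit ATP5PF fell by 0.35. All of these 7 genes lost their calls with normexp scaling: PC (adjusted p = 0.0628), SDHD (0.0549), NDUFB3 (0.0665), SDHC at -0.02 (0.946), SDHA at 0.07 (0.754), NDUFV2 at 0.14 (0.512) and ATP5PF at -0.49 (0.126). In the pentose phosphate and one-carbon list 6 of 19 rose, 6 fell and 7 did not pass (7 and 6 adjusted over the list alone; median 0.05, adjusted p = 0.368). Of its members PSAT1, of serine synthesis, rose by 2.64, and MTHFD2 and SHMT2, of mitochondrial folate use, by 1.66 and 1.02.

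Genes of sterol synthesis fell together. Of 25 cholesterol synthesis genes 0 rose, 21 fell and 4 did not pass (0 and 21 adjusted over the list alone), with a median of -1.18 (adjusted p = 1.14e-10). That list had adjusted p = 0.316 with an estimated correlation, and a median of -1.32 with slide as a block (adjusted p = 9.8e-12). After HMGCS1, the squalene epoxidase SQLE fell by 2.66, MSMO1, a sterol oxidase, by 2.32, and IDI1, an isomerase of isoprenoid units, by 2.29. In the deposited value table SQLE was higher by 0.33. Of 16 fatty acid synthesis genes 1 rose, 7 fell and 8 did not pass (1 and 7 adjusted over the list alone; median -0.39). The list did not pass (adjusted p = 0.0669), but did with slide as a block (0.0418) and in several other alternatives. Among these were normexp scaling (0.00249) and the mean of probes (0.0449). The desaturase SCD fell by 1.51, ACSL1, which activates fatty acids, by 1.34, the fatty acid synthase FASN by 1.19 and the desaturase FADS1 by 0.86. Under normexp scaling FASN differed by -0.59 (adjusted p = 0.269) and MSMO1 by -1.47 (0.058), and neither passed.

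Among the 41 lists the unfolded protein response had the largest median shift. Of its 24 measured genes 23 rose, 0 fell and 1 did not pass (23 and 0 adjusted over the list alone), with a median of 1.49 (adjusted p = 4.15e-15). The unfolded protein response list had adjusted p = 0.316 with an estimated correlation, and a median of 1.38 with slide as a block (adjusted p = 7.75e-15). HERPUD1, of protein degradation at the endoplasmic reticulum, rose by 2.96, the chaperone cofactor SDF2L1 by 2.83 and MANF, a secreted protein of the same compartment, by 2.31. Of 30 genes of the amino acid response driven by ATF4, 25 rose, 1 fell and 4 did not pass (25 and 1 adjusted over the list alone), with a median of 1.18 (adjusted p = 2.28e-14). This list had adjusted p = 0.316 with an estimated correlation, and a median of 1.10 with slide as a block (adjusted p = 7.75e-15). The amino acid transporter SLC7A5 rose by 3.0 and the pseudokinase TRIB3 by 2.60, next to DDIT3 and ASNS. NRF2 antioxidant genes rose in 12 of 22 cases, with 0 falls and 10 not passing (13 and 0 adjusted over the list alone; median 0.36, adjusted p = 4.74e-05). The antioxidant list had adjusted p = 0.548 with an estimated correlation, and a median of 0.30 with slide as a block (adjusted p = 0.000899). The reductase AKR1B10 rose by 1.65, the glutathione peroxidase GPX2 by 1.25, UGDH, which makes glucuronate, by 1.22 and the thioredoxin reductase TXNRD1 by 0.96. Of 12 metallothionein list members, near-identical paralogs for the most part, 8 rose, 0 fell and 4 did not pass (8 and 0 adjusted over the list alone; median 0.22, adjusted p = 0.0217). This list had adjusted p = 0.586 with an estimated correlation, a median of 0.14 with slide as a block (adjusted p = 0.0326), and a median of 0.053 with normexp scaling, where it did not pass (adjusted p = 0.95). MT1X rose by 0.39 and MT1G by 0.28, the latter with an adjusted p of 0.174 with slide as a block and without its call in all but 1 of the fits that left out a sample. Normexp scaling ended the calls of both (adjusted p = 0.357 and 0.451). Heat shock genes rose in 3 of 19 cases and fell in 8, and 8 did not pass (5 and 10 adjusted over the list alone; median -0.20, adjusted p = 0.255). The heat shock list had a median of -0.43 with slide as a block (adjusted p = 0.246). It passed with normexp scaling, with a median of -0.28 (adjusted p = 0.00256). HSPA6 rose by 1.57 (by 1.02 with normexp scaling, adjusted p = 0.212), while the constitutive chaperone HSPA8 fell by 1.37, HSPA1A by 0.83 and HSPH1 by 0.82.

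Genes of DNA replication fell. Of 46 measured members of the DNA replication and G1/S list 1 rose, 43 fell and 2 did not pass (1 and 44 adjusted over the list alone), with a median of -0.67 (adjusted p = 2.45e-13). The replication list had adjusted p = 0.25 with an estimated correlation, and a median of -0.72 with slide as a block (adjusted p = 3.01e-14). Besides GINS2, the helicase subunit MCM6 fell by 1.24. Cyclin E2, CCNE2, fell by 1.09, but differed by 0.42 with normexp scaling, where it did not pass. Of 49 mitosis and G2/M genes 12 rose, 8 fell and 29 did not pass (12 and 7 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0318). The mitosis list had adjusted p = 0.739 with an estimated correlation, and a median of 0.10 with slide as a block, where it did not pass (adjusted p = 0.0601). Nor did the mitosis list pass without 5-HT replicate 3 (median 0.07, adjusted p = 0.117) or with normexp scaling (median 0.051, adjusted p = 0.903). CDC20, which activates the anaphase-promoting complex, rose by 1.12, the kinesin KIF20A by 0.93 and the kinetochore motor CENPE by 1.07 (adjusted p = 0.0508 with slide as a block), while the centromere protein CENPM fell by 0.70. CENPE and CENPM did not pass with normexp scaling (adjusted p = 0.0539 and 0.0562). Replication-dependent histone genes, also near-identical paralogs, rose in 5 of 32 cases and fell in 3, and 24 did not pass (4 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.0941). The linker histone H1-1 rose by 0.98 and H3C1 fell by 0.70.

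The lists of growth and cell death did not pass. Of 30 MYC and nucleolar targets 4 rose, 7 fell and 19 did not pass (4 and 7 adjusted over the list alone; median -0.06, adjusted p = 0.812). MYC rose by 0.75 (SE 0.10), but by 0.59 with normexp scaling, where it did not pass (adjusted p = 0.122), and another MYC probe differed by 0.01 (adjusted p = 0.942). TFRC, the transferrin receptor, fell by 2.19. Of 47 cytoplasmic ribosomal protein genes 0 rose, 10 fell and 37 did not pass (0 and 8 adjusted over the list alone; median -0.08, adjusted p = 0.0941, and 0.00601 with slide as a block). The ribosomal list also passed with normexp scaling, with a median of -0.24 (adjusted p = 2.73e-07). RPL6 fell by 0.42 and RPL3 by 0.38 (adjusted p = 0.0547 for RPL3 with normexp scaling). For p53 targets 6 of 26 rose, 9 fell and 11 did not pass (6 and 9 adjusted over the list alone). Their median was -0.02 and their mean 0.01, in the direction of the test, which did not pass (adjusted p = 0.826). GDF15, a stress-induced cytokine, rose by 2.91 and SESN2 by 1.24, while TP53INP1 fell by 1.28 and SESN1 by 1.16 (by 0.61 with normexp scaling, adjusted p = 0.158). In the list of the BCL2 family and caspases 7 of 29 rose, 6 fell and 16 did not pass (7 and 6 adjusted over the list alone; median 0.01, adjusted p = 0.407). BIRC3, an inhibitor of apoptosis, rose by 1.38, the pro-apoptotic BIK by 1.14, CASP9 by 1.06 and the anti-apoptotic BCL2L1 by 1.04. Autophagy and lysosome genes rose in 11 of 38 cases and fell in 13, and 14 did not pass (11 and 14 adjusted over the list alone; median -0.11, adjusted p = 0.998). WIPI1 rose by 0.80 and the protease CTSD by 0.60 (adjusted p = 0.0557 and 0.0653 with normexp scaling). Of 29 genes of FOXO and PI3K-AKT feedback 6 rose, 14 fell and 9 did not pass (6 and 14 adjusted over the list alone; median -0.17, adjusted p = 0.133). The feedback list passed with normexp scaling, with a median of -0.15 (adjusted p = 0.00123). With TXNIP and ARRDC4, PIK3IP1, an inhibitor of PI3-kinase, fell by 1.87, whereas KLF9 rose by 1.59.

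Of 38 interferon-stimulated genes 25 rose, 1 fell and 12 did not pass (27 and 1 adjusted over the list alone), with a median of 0.33 (adjusted p = 3.42e-08). The interferon list had adjusted p = 0.548 with an estimated correlation, and a median of 0.28 with slide as a block (adjusted p = 1.41e-06). SAMD9 rose by 1.15, the transcription factor IRF1 by 0.96, and OAS1 and OASL, of the antiviral oligoadenylate synthetase family, by 0.92 and 0.86, the latter with an adjusted p of 0.0628 with normexp scaling. For antigen presentation 6 of 22 rose, 0 fell and 16 did not pass (6 and 0 adjusted over the list alone); the median was -0.02 and the mean 0.06, in the direction of the test (adjusted p = 0.377). The immunoproteasome subunit PSMB9 rose by 0.52 and the peptide transporter TAP1 by 0.37. The probes of TAP2 disagreed: the reported probe rose by 0.50, and another, above background on 3 arrays, differed by -1.90 and was not called. With normexp scaling PSMB9, TAP1 and TAP2 lost their calls (adjusted p = 0.187, 0.264 and 0.335). NF-kB targets and chemokines rose in 9 of 35 cases and fell in 15, and 11 did not pass (10 and 16 adjusted over the list alone; median -0.16, adjusted p = 0.62). The interleukins IL1B and IL1A rose by 2.38 and 2.17, while LTB and TNF, cytokines of the tumour necrosis factor family, fell by 3.0 and 1.95. TNF differed by -0.46 with normexp scaling (adjusted p = 0.468) and by -0.54 at its other probe (0.0567), neither of which passed. In the TGF-beta list 11 of 24 rose, 6 fell and 7 did not pass (12 and 7 adjusted over the list alone; median 0.18, adjusted p = 0.0941). ID1 rose by 2.36 and the pseudoreceptor BAMBI by 1.48. ID2 fell by 1.62, above background on 1 of 3 5-HT arrays; its adjusted p was 0.119 with slide as a block, and 0.0609, 0.0578 and 0.0517 without control replicate 1, control replicate 3 and 5-HT replicate 2. With normexp scaling the sign of ID2 turned, to a log2 difference of 0.27, which did not pass (adjusted p = 0.731). Immediate-early genes rose in 14 of 34 cases and fell in 9, and 11 did not pass (15 and 10 adjusted over the list alone; median 0.17, adjusted p = 0.0668). FOSL1, ATF3 and FOS, all AP-1 or related factors, rose by 2.28, 1.78 and 1.60, and EGR2 fell by 1.45 (by 0.11 with normexp scaling, adjusted p = 0.871). Of 23 YAP/TEAD targets 9 rose, 4 fell and 10 did not pass (10 and 5 adjusted over the list alone; median 0.16, adjusted p = 0.0633). Tissue factor, F3, rose by 1.13, WWC1 by 0.99 and GADD45A by 0.95, and the kinase NUAK2 fell by 1.07.

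Of 42 epithelial and ductal genes 29 rose, 5 fell and 8 did not pass (30 and 5 adjusted over the list alone), with a median of 0.41 (adjusted p = 2.74e-09). The epithelial list had adjusted p = 0.316 with an estimated correlation, and a median of 0.39 with slide as a block (adjusted p = 9.82e-09). The epithelial transcription factor ELF3 rose by 2.87, the tight junction protein TJP3 by 2.27, the surface glycoprotein CEACAM5 by 2.10 and the secreted trefoil peptide TFF1 by 2.02. Squamous and keratinization genes rose in 7 of 32 cases and fell in 17, and 8 did not pass (7 and 17 adjusted over the list alone), with a median of -0.30. That list did not pass (adjusted p = 0.0668), but did with slide as a block (0.0418) and in several other alternatives. Among these were quantile normalization (0.0496) and normexp scaling (6.91e-05). SPRR2D, of the cornified envelope, fell by 1.67 and the calcium-binding S100A8 by 1.43, while keratin 13, KRT13, rose by 2.01 and the peptidase KLK8 by 1.40. For mesenchymal genes 6 of 25 rose, 8 fell and 11 did not pass (6 and 9 adjusted over the list alone); the median was -0.05 and the mean 0.10, in the direction of the test (adjusted p = 0.737). LOXL2, which cross-links collagen, rose by 1.93, the transcription factor SNAI1 by 0.78 (adjusted p = 0.19 with normexp scaling) and the integrin ITGA5 by 0.71. The collagen COL5A1 fell by 0.88, but differed by 0.17 in the deposited value table and by -0.20 with normexp scaling (adjusted p = 0.631), and passed in neither. Of 24 extracellular proteases and inhibitors 14 rose, 4 fell and 6 did not pass (15 and 5 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.00211). The protease list had adjusted p = 0.25 with an estimated correlation, a median of 0.31 with slide as a block (adjusted p = 0.00217), and a median of 0.20 with normexp scaling, where it did not pass (adjusted p = 0.133). The collagenase MMP1 rose by 3.01, the elastase MMP12, above background on 1 of 3 control arrays, by 2.88 (by 1.34 with normexp scaling, adjusted p = 0.0737), and the protease inhibitor TIMP3 by 1.91. In the list of EGFR and Wnt ligands and regulators 10 of 26 rose, 8 fell and 8 did not pass (10 and 8 adjusted over the list alone); the median was -0.17 and the mean 0.21, in the direction of the test (adjusted p = 0.355). The EGF receptor ligands EREG, AREG and HBEGF rose by 2.48, 2.12 and 1.79, and LEF1, a Wnt transcription factor, fell by 1.60 (by 0.20 with normexp scaling, adjusted p = 0.762).

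**Figure D2:**
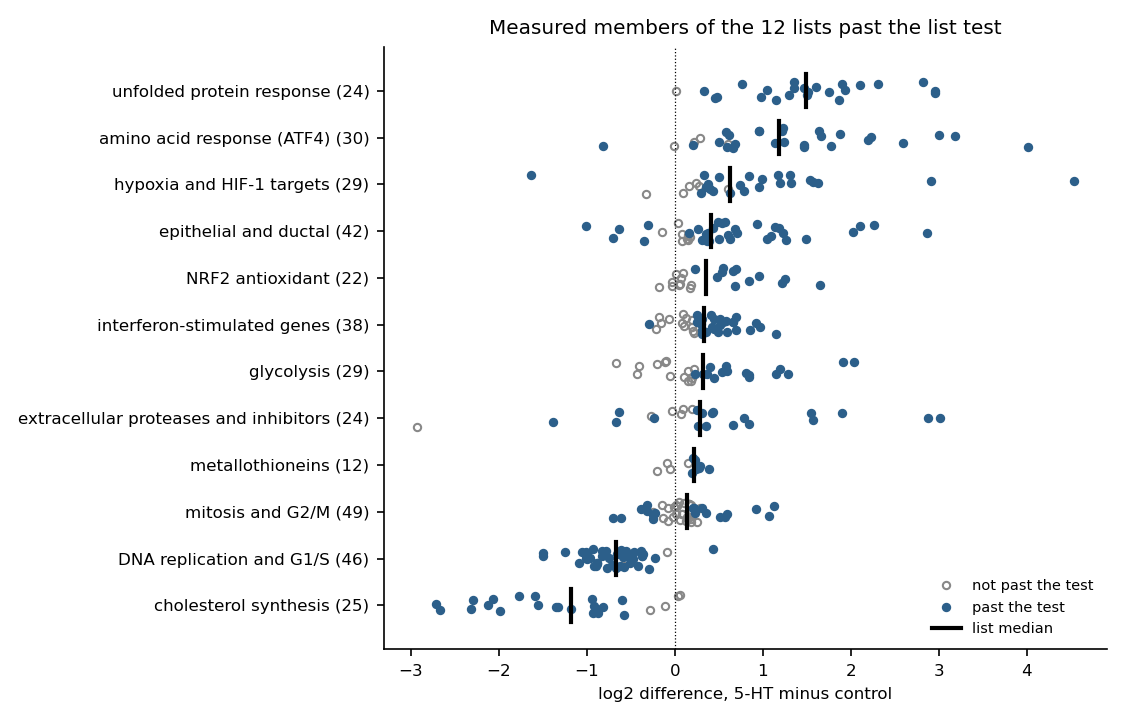
Log2 difference between 5-HT and control (horizontal axis) of each measured member of the 12 lists that passed, 1 point per gene, filled where the gene passed its own test; the line is the list's median and the number in brackets the members measured. Medians ran from -1.18 for cholesterol synthesis to 1.49 for the unfolded protein response.

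Few serotonin receptor transcripts were measurable. Of 17 receptor genes 7 were tested, of which 0 rose, 1 fell and 6 did not pass (0 and 1 adjusted over the list alone; median -0.22, adjusted p = 0.386). HTR7, a receptor that raises cAMP, fell by 0.51 (SE 0.05). HTR1D differed by -0.22 (SE 0.16, adjusted p = 0.306), but passed at -0.39 without 5-HT replicate 2 (adjusted p = 0.0293) and at -0.32 with array weights (0.0477). The receptor HTR2B and the serotonin transporter SLC6A4 were above background on 0 arrays. Of 12 tested genes of serotonin synthesis, transport and breakdown 4 rose, 2 fell and 6 did not pass (4 and 2 adjusted over the list alone). Their median was -0.01 and their mean 0.00, and the test, upward, did not pass (adjusted p = 0.368). The transglutaminase TGM2, which can couple serotonin to proteins, rose by 2.18, and by 1.21 at another probe. IDO1, which consumes tryptophan, rose by 0.63 and the dehydrogenase ALDH2 by 0.41 (adjusted p = 0.399 with normexp scaling), while KYNU, of tryptophan breakdown, fell by 0.93. TPH1, which makes serotonin, differed by -0.24 (SE 0.19, adjusted p = 0.347), with the opposite sign, 0.17, with slide as a block. It passed at -0.44 without 5-HT replicate 1 (adjusted p = 0.0174) and at -0.43 with array weights (0.0192). The monoamine oxidase MAOA differed by 0.34 (SE 0.24, adjusted p = 0.293). Calcium and cAMP targets rose in 7 of 19 cases and fell in 6, and 6 did not pass (7 and 7 adjusted over the list alone); the median was -0.03 and the mean 0.04, in the direction of the test (adjusted p = 0.325). RGS16, which dampens G-protein signalling, rose by 2.15 and RCAN1, an inhibitor of calcineurin, by 0.84, while RGS2 fell by 0.56. Of 19 circadian clock genes 8 rose, 3 fell and 8 did not pass (9 and 3 adjusted over the list alone; median 0.07, adjusted p = 0.127). The clock output factor DBP rose by 1.25 (by 0.47 at another probe), and NR1D1 and BMAL1, of the core loop, by 0.83 and 0.69.

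**Figure D3:**
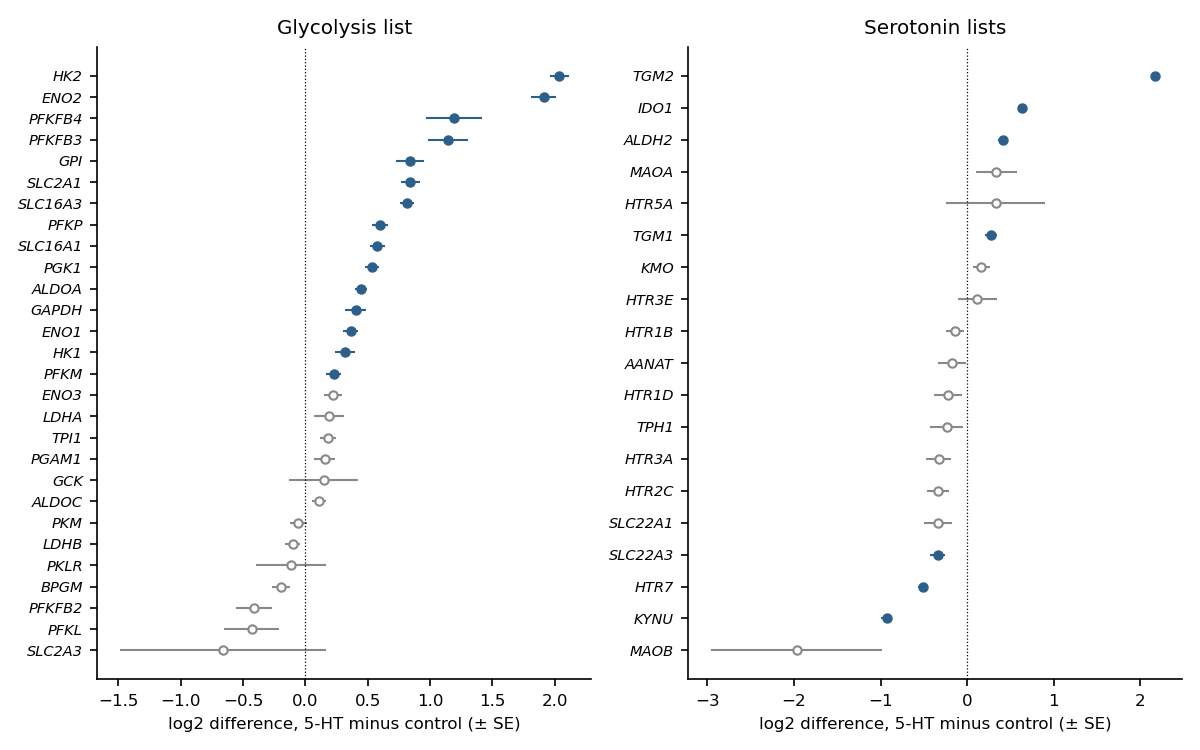
Log2 difference between 5-HT and control with its SE (horizontal axis, n = 3 per group) for measured genes of the glycolysis list (left, 28 of the 29 drawn) and for each of both serotonin lists (right), filled where the gene passed the test. By the reported probe of each gene, HK2 was highest on the left at 2.04, and TGM2 on the right at 2.18.

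None of the 5 lists of markers of other cell types passed. Of 10 fibroblast and stellate cell markers 1 rose, 4 fell and 5 did not pass (1 and 5 adjusted over the list alone; median -0.68, adjusted p = 0.11). The proteoglycans DCN and LUM fell by 3.18 and 2.56; in the deposited value table DCN differed by -0.10 and did not pass (adjusted p = 0.168). The collagen COL3A1 fell by 1.25, and the receptor PDGFRA by 0.72, above background on 1 of 3 5-HT arrays and with an adjusted p of 0.261 with slide as a block. With normexp scaling all 4 lost their calls: DCN differed by -1.19 (adjusted p = 0.153), LUM by -0.82 (0.334), COL3A1 by 0.066 and PDGFRA by 0.59. Leukocyte markers rose in 4 of 12 cases, with 0 falls and 8 not passing (3 and 0 adjusted over the list alone; median 0.13, adjusted p = 0.317), among them the macrophage protein CD68 at 0.63. For acinar and islet markers 2 of 10 rose, 0 fell and 8 did not pass (2 and 0 adjusted over the list alone). Their median was -0.02, and the test, upward, did not pass (adjusted p = 0.532); the lipase CEL rose by 1.86. Endothelial markers rose in 2 of 8 cases and fell in 2, and 4 did not pass (2 and 3 adjusted over the list alone; median -0.25, adjusted p = 0.62). The receptor TEK fell by 1.45 and the clotting factor carrier VWF by 0.84, while PECAM1 rose by 0.54. All 3 lost their calls with normexp scaling, TEK at -0.15 (adjusted p = 0.834), VWF at -0.39 (0.297) and PECAM1 at 0.73 (0.163). Of 6 erythroid markers 1 rose, 0 fell and 5 did not pass (0 and 0 adjusted over the list alone; median 0.01, adjusted p = 0.781). The globin gene HBG1, above background on 2 of 3 control arrays, rose by 0.54, with an adjusted p of 0.3 with slide as a block. HBG1 and PDGFRA lost their calls in many other alternatives as well.

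In total 12 of the 41 lists passed, 10 up and 2 down. The 9 other splits of the 6 arrays into 3 and 3 called 7 to 12 lists. Each of these had control and 5-HT arrays on both sides, so part of the group difference stayed in the comparison. Their counts do not show what chance gives. With an estimated correlation 0 passed, 6 had an unadjusted p under 0.05, and fry called 29. The estimate was 0.008 for glycolysis and -0.002 for the proteases, both below the preset 0.01. A higher correlation between genes therefore does not account for the loss of these calls. In that form the test also has only the few residual degrees of freedom of 6 arrays, so its power is low. With normexp scaling 15 passed, 9 of them among the 12. Lists of fatty acid synthesis, squamous genes, ribosomal proteins, immediate-early genes, YAP/TEAD targets, FOXO feedback, heat shock, oxidative phosphorylation and histones, not called here, passed in at least 1 alternative other than fry. With slide as a block 11 of the 12 kept their call. Those estimates equal 5-HT replicate 1 minus the controls, so they too rest on 1 treated sample and are no independent support. Within the slide that holds both groups all 12 passed, but 2 of the 3 5-HT arrays lay on the other slide, so those values rest on 1 treated sample, with a spread from the controls only, and are no independent support.

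For 48 of 22900 probes well above background on all 6 arrays and with a mean log2 signal over 6, the deposited value table gave a group difference more than 0.5 away from that of the scanner files, always toward higher values with serotonin. These probes belonged to 40 genes, among them 4 of the glycolysis list (ENO1, LDHA, PFKL and PGK1) and 7 of the cholesterol synthesis list. Relative to the median probe, the reported probe of MYC differed by 0.81 in the scanner files and 2.79 in the deposited table, LDHA by 0.25 and 2.33, PFKL by -0.37 and 2.30, and ENO1 by 0.42 and 2.49. The corresponding values were -2.60 and 0.37 for SQLE, -2.13 and -0.15 for TFRC, -3.12 and -0.07 for DCN, -2.23 and -0.26 for IDI1, and -0.80 and 1.19 for FADS1. The values reported here come from the scanner files. With the deposited table the glycolysis list shift, its median, was 0.45 (adjusted p = 8.19e-07).

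**Figure D4:**
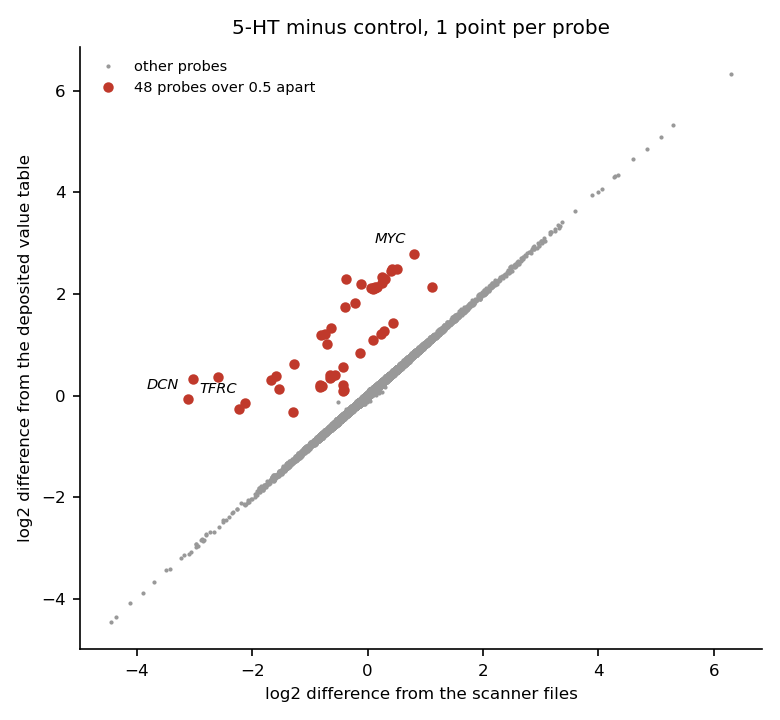
Difference between 5-HT and control for each of 22900 probes with a mean log2 signal over 6, from the scanner files (horizontal axis, log2) and from the deposited value table (vertical axis, log2), each relative to its median probe. The 48 probes more than 0.5 apart (red) all lie above the line of other probes (grey), MYC at 0.81 and 2.79.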

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

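Signal over background limits some values: a transcript below background in 1 group has only a lower bound. Of the 26 alternatives, those of the list test or threshold gave no values for named genes. Those of the threshold or family of genes gave none for lists. Over the rest, 181 named genes gave 3787 values with an unchanged call or none, 160 that lost the call and 9 that gained it. In 11 more a called value took the opposite sign. The lists gave 865, 23, 55 and 0 in that order. Among the 3787, uncalled values of PKM, HTR1D and TPH1 also changed sign in some alternatives. Of the 160 lost calls, 61 came with normexp and 75th percentile scaling, 20 with slide as a block and 21 within the slide that holds both groups. The cause was not tested except where stated. Background correction by normexp with 75th percentile scaling left 2244 changed genes (1146 up, 1098 down), moved the median of all genes from -0.0732 to 0.169, and turned BBOX1 (0.051), CLRN3 (0.13), CCNE2 (0.42), ID2 (0.27), COL3A1 (0.066) and PDGFRA (0.59), none past the threshold there. The same correction with quantile normalization left 9546 changed genes (4418 up, 5128 down), moved that median to -0.0185, and ended the calls of only PDGFRA and HBG1, so most of those losses need the combination with that scaling. TAP2 was -0.15 as the mean of its probes and -1.90 with its most variable probe, since its probes disagree. In the deposited value table CA12 (0.35), SQLE (0.33) and COL5A1 (0.17) turned, through offsets in that table. This alternative chose the brightest probe again, so FADS1, whose reported probe also turned there, was represented by another probe and kept its direction and call. Array weights gave 13905 changed genes, 5610 up and 8295 down. By construction, a 2-fold minimum left 1368 (678 up, 690 down) and an adjusted p under 0.01 left 5759 (2640 up, 3119 down). Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05), with glycolysis at 0.32 (adjusted p = 0.25) and hypoxia at 0.62 (adjusted p = 0.519), while fry called 29. The glycolysis and hypoxia lists passed in the other alternatives, with medians of 0.20 to 0.45 and 0.40 to 0.87. The slide that holds both groups, an alternative chosen after seeing the data, gave 5438 genes (2376 up, 3062 down) from 4 arrays. Leaving out 1 sample gave 6855 to 11027 changed genes, 3076 to 4593 up, 3764 to 6434 down, and 11 to 15 lists; glycolysis ran from 0.26 to 0.40 and hypoxia from 0.52 to 0.75. The mitosis list lost its call with quantile normalization (adjusted p = 0.08), with slide as a block (0.0601), without control replicate 2 (0.0508) and without 5-HT replicate 3 (0.117), among others, and with normexp and 75th percentile scaling the mitosis, metallothionein and protease lists did (adjusted p = 0.903, 0.95 and 0.133). Median scaling gave 4640 genes up and 4486 down. With the replicate number as a block 7736 genes changed, 3297 up and 4439 down. By the labels, same-numbered samples shared only a number. Their deviations from the group means correlated at -0.07, 0.02 and 0.06 across genes, and 2 of 6 samples correlated best with their own number. Deviations of the 5-HT arrays also hold the difference between slides, which could mask a pairing, so a pairing is not excluded.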

Other observations

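The tests of retinoic acid targets, of the unfolded protein response against slide, of a weaker replicate 1 and of whole-unit offsets were chosen only after the results were seen, as were the genes named here. Beyond the lists, transcripts tied to retinoic acid rose. CYP26A1, which degrades retinoic acid, and RARB, one of its receptors, were above background on 0 control arrays and at least 3.29-fold and 4.25-fold higher with serotonin (adjusted p = 0.000589 and 0.000597). Among other known targets of these receptors STRA6, a retinol transporter, rose by 3.12, DHRS3, which reduces retinal, by 2.53, RARRES1 by 2.53 (above background on 2 of 3 control arrays) and CYP26B1 by 1.07, while NTRK2 fell by 2.91. A list of such targets without CYP26A1, RARB and TGM2, whose values were already known, had 18 measured members, of which 12 rose, 2 fell and 4 did not pass (13 and 2 adjusted over the list alone; median 0.77). Its camera p was 5.05e-06, and 0.0406 with an estimated correlation. The list was written after the results had been seen, and its member ICAM1 also belongs to the NF-kB list tested above. Its counts and p-values are therefore no independent support. A wider rise of retinoic acid targets is thus a hypothesis that may merit a test; no retinoid was measured, and several members also answer to other signals.

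Other large changes lay in genes of varied function. NOX1, an oxidase that makes superoxide, rose by 3.84, FOXJ1, a transcription factor of ciliated cells, by 3.54, and CREB3L3, a transcription factor held at the endoplasmic reticulum, by 3.30. HSD11B1, which activates glucocorticoids, rose by 3.24 and IL1RL1, the interleukin-33 receptor, by 3.12. GLI1, a Hedgehog target, was at least 3.57-fold higher (adjusted p = 0.000392). The chemokine CXCL14 fell by 3.12, the glycoprotein GPNMB by 3.03 and INHBA, a subunit of activin, by 2.63.

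The rise of unfolded protein response genes was weighed against a slide effect. Within the slide that holds both groups the list had a median of 1.38, which a slide effect shared by its arrays would not give, though 1 treated sample there leaves open what was peculiar to that sample. A separate list of 29 genes of translocation, glycosylation and degradation at the endoplasmic reticulum had 22 rises, 0 falls and 7 not passing (23 and 0 adjusted over the list alone; median 0.40, camera p = 1.31e-09, and p = 0.0606 with an estimated correlation), with GFPT1 at 1.75. These values are consistent with a wider stress of the endoplasmic reticulum, as a hypothesis; differences in handling or medium between the groups remain open, as do shortages of glucose and of amino acids, which were not tested.

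5-HT replicate 1 stood apart from replicates 2 and 3 and lay on another slide. In replicate 1, 4 of the 12 lists that passed shifted more than in replicates 2 and 3 (hypoxia 0.874 against 0.524, cholesterol synthesis -1.32 against -1.10, DNA replication -0.723 against -0.683, extracellular proteases 0.307 against 0.3). The other 8 shifted less, so what argues against a uniformly weaker response there is mainly hypoxia and cholesterol synthesis. Of 9568 changed genes 3893 (40.7%) had the larger response in replicate 1, with a median size of 0.45 against 0.50. Across genes, the gap between replicates 2 and 3 and replicate 1 correlated at -0.23 with the response of replicate 1. Replicate 1 enters both measures with opposite sign, and 20 simulations of equal responses gave a mean of -0.32, so a negative value is built in. The observed value lay outside the range of the simulations, whose spread was drawn from the controls only. Replicate 1 was the only 5-HT sample on its slide, so a slide effect and a difference between samples cannot be told apart.

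The departures of the deposited value table from the scanner files had a regular form. At the 48 probes, 147 array values had moved by more than 0.5 on the log2 scale: 94 were lowered in control arrays and 53 raised in 5-HT arrays, with 0 moved the other way. Of these 97.3% lay within 0.1 of a whole log2 unit, where chance gives 20%, which argues against a normalization applied to the whole table; nearly all other probes had shifts between -0.053 and 0.076. In the scanner files the group differences of the unprocessed and the processed signals at these spots had a median gap of 0.05, as at other probes (0.05), which argues against faulty processed signals there. How the offsets arose is not given in the sources used here. They lie between the deposited and the scanner value of the same probe on the same array, so they are no difference between the cells. The values given here for the affected genes come from the scanner files.

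The 10 possible splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 9574 genes and the highest other split 3, so that 1 split gave as many. It called 12 lists and the 9 others 7 to 12, so that 3 splits gave as many. Each of the 9 others had control and treated arrays on both sides, so the group difference raised the spread within each side. Low gene counts follow from that by construction, so neither the gene nor the list counts of those splits show what chance gives.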
